A study of Arabidopsis thaliana with 9 samples.

How the data were processed

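The study used Arabidopsis plants carrying LAT52-HF-RPL18, a FLAG-tagged ribosomal protein L18 driven by a pollen promoter. Plants were grown at 22 °C with 18 h of light and 6 h of dark. Per the labels, ribosome complexes were separated through 20% to 60% sucrose gradients, the polysome fractions were pulled down with FLAG antibody beads, and the purified mRNA was amplified once, labelled with biotin and hybridised to Affymetrix arrays. The 9 arrays fall into 3 groups of 3 biological replicates. The bud group came from floral buds of stage 11 to 12, the in vivo group from self-pollinated flowers of stage 14, and the in vitro group from cultured pollen tubes. The series text calls the bud material unpollinated styles, while each bud sample is labelled as floral buds, and the sample labels were followed. The 4 measured genes of the tapetum, a tissue of the anther, had bud signals of 3782 (A9), 3202 (SHT), 755 (AMS) and 718 (EMS1). Of these, EMS1 was about as bright in vivo. The signals argue against styles alone.

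The deposited values are intensity values, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. The values are on a linear scale. The mean of each array, after trimming the highest and lowest 2% of values, was about 500, so each array had been scaled to one target and not further adjusted between arrays. Detection calls were not used here. A signal is therefore a level relative to the rest of its own array.

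Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. The gene table used here gave 1 gene for 13513 probe sets and several genes for 503, and did not list 8730. It was thinner for well-studied genes: 1530 of 10492 protein-coding genes with a symbol (14.6%) had a probe set named here, against 10763 of 17070 known by a locus code alone (63.1%). Gene lists were therefore covered in small part, and probe sets without a named gene were counted but not described. No coordinates are printed, because no source used here states the assembly behind the probe set annotation.

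Values were transformed as log2(value + 16) without other scaling and without a filter on dim probe sets. limma 3.58.1 in R 4.3.3 was fitted to all 9 arrays with 1 mean per group, and each of the 3 contrasts was adjusted by the Benjamini-Hochberg method over all tested probe sets. A probe set was called changed at an adjusted p under 0.05. Every adjusted p printed for a gene is from this limma test, which takes both directions. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so no permutation p is given for single genes. Log2 folds carry the standard error (SE) of the fit, and signals carry the standard deviation (SD) of 3 arrays. The number of arrays limits the precision.

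Sets called in both of 2 contrasts were set beside the number that independent calls would share and beside 100 simulated data sets without any effect. Without an effect almost no probe set passes the adjusted threshold, so the simulated overlap is near 0 by construction. The number from independent calls does not allow for the arrays that both contrasts share. The simulation holds these shared arrays, but an overlap near 0 cannot show their effect. The 3 bud arrays cannot be split into 2 parts of 2 arrays, so the shared-array correlation was set beside simulation only.

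Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over the lists tested within a contrast; adjusted p-values with the correlation estimated from the data stand beside them. Of 20 lists, 14 had at least 3 measured members and were tested. Pollen ion transport and calcium signalling had 1 measured member; pollen sugar and solute carriers had 2, as did heat shock proteins and factors. None of the members of the lists for epidermis, cuticle and wax, for jasmonate synthesis and response, or for cytosolic ribosomal proteins had a probe set named here. The ribosomal list was read from gene symbols and synonyms and was incomplete. It missed the ribosomal protein genes AT4G16720, AT5G20290, AT3G02080 and AT5G27850, which had probe sets and are described below. Counts "adjusted over the list alone" use the Benjamini-Hochberg method over the members of one list. A Gene Ontology test was planned and not run, because the tables used here hold no terms. Of 29 gene families grouped after the data were seen, 5 are described, and the results of the others are not reported here.

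The named genes follow a rule. For each contrast they are the 12 largest positive and the 12 largest negative log2 folds among called probe sets with 1 named gene, no overlap between the arrays of the compared groups, and a mean signal of the higher group above the median of all probe sets. Added to these are 12 genes higher in vivo than in both other groups, and up to 4 members per list with the largest absolute moderated statistic. ANX1, ANX2, VGD1, MYB97, MYB101, MYB120, LIP1, LIP2 and the RPL18 genes were to be named whatever their values; of these, VGD1, the MYB genes, the LIP genes and the RPL18 copy carried by the transgene had no probe set named here. Groups, contrasts, tests, lists, the naming rule and the alternatives listed next were chosen before the data were examined.

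The alternatives were offsets of 1 and 64, quantile normalization, equal array medians, leaving out the dimmest 30% of probe sets, a threshold of at least 2-fold, an intensity trend with robust fitting, the replicate number as a block, a fit to the 6 arrays of the compared groups alone, and leaving out each array in turn; the list test was also run on ranks.

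The procedure was tested on simulated data with 22746 genes, of which 100 were changed at each size. For a log2 change of 3 it recovered 77% in the simulated contrast of in vivo with bud, 87% for in vitro with bud and 75% for in vivo with in vitro. For a log2 change of 1 it recovered 2%, 1% and 1%, and it called 1, 3 and 2 unchanged genes. Far fewer genes were changed in the simulation than were called in the real contrasts with in vitro (13859 and 13495 probe sets). With so many calls the adjusted threshold is less strict. Folds near 1 were called there, such as XIC in vitro over bud (0.96, limma adjusted p = 0.0329). The simulated recoveries therefore do not describe the contrasts with in vitro. Figures were drawn with Python 3.11.15.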

Results

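The arrays measured polysomal mRNA pulled down with a tagged ribosomal protein that is made under a pollen promoter. The samples were floral buds, self-pollinated flowers (in vivo) and cultured pollen tubes (in vitro), with 3 arrays per group. The bud and in vivo pull-downs need not hold pollen RNA alone. Measured photosynthesis genes had a mean log2 signal of 13.4 in bud, 13.2 in vivo and 6.27 in vitro. The median signal per array was 187 ± 10.6 (SD, n = 3) in bud, 183 ± 7.70 (SD, n = 3) in vivo and 83.2 ± 24.5 (SD, n = 3) in vitro. Signals above 500 were found for 27.7% of probe sets in bud, 27.7% in vivo and 16.3% in vitro. The brightest 1% of probe sets held 26.2 ± 1.83% (SD, n = 3) of all signal in bud, 23.4 ± 4.83% in vivo and 51.7 ± 10.7% in vitro. Across probe sets, which are not independent replicates, log2 values correlated at 0.940 to 0.965 within bud, 0.947 to 0.970 within the in vivo group and 0.859 to 0.933 within the in vitro group. Bud and in vivo arrays correlated at 0.890 to 0.918, bud and in vitro arrays at 0.277 to 0.381, and in vivo and in vitro arrays at 0.351 to 0.472. The median signal of the hybridisation controls was 78112 on in vitro replicate 3 and 1719 on in vivo replicate 1, against 5995 to 17569 on the other 7 arrays. The ratio of the 3' to the 5' GAPDH control was 1.28 to 3.82 in bud, 1.21 to 2.09 in vivo and 1.44 to 1.68 in vitro. For ubiquitin it was 1.96 to 3.18, 1.36 to 3.01 and 1.35 to 2.52. Bud replicate 1 had the highest of both ratios. Their effect on the calls was not tested, apart from leaving out single arrays.

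Of the RPL18 genes, the copy carried by the transgene had no probe set named here. AT5G27850, another RPL18 gene, had a signal of 12449 ± 1442 (SD, n = 3) in bud, 10176 ± 1544 in vivo and 122 ± 51.7 in vitro. AT2G47570 had 64.03 ± 28.9 in bud, 52.1 ± 9.92 in vivo and 95.7 ± 67.3 in vitro.

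The comparison of in vivo with bud asked how the ribosome-bound mRNA of pollinated flowers differs from that of buds. The groups differ in floral stage (11 to 12 in bud, 14 in vivo) as well as in pollination, so these cannot be told apart. Of the 5 surface receptor and 4 cell wall genes of the pollen tube, 2 and 3 were called higher in vivo, and both lists passed with the preset correlation but not with an estimated one (adjusted p = 0.136 for each). LRX9 (AT1G49490) and LRX8 (AT3G19020), leucine-rich repeat extensins of the pollen tube wall, rose by log2 folds of 3.29 ± 0.49 (SE, adjusted p = 0.00253) and 3.05 ± 0.47 (SE, adjusted p = 0.00347). In vivo replicate 3 was the brightest, with 6903 for LRX9 against 2325 and 1931 on the others, and 4409 for LRX8 against 1256 and 1466. The receptor-like kinases BUPS1 (AT4G39110) and ANX2 (AT5G28680), which act in pollen tube integrity, rose by 2.44 ± 0.39 (SE, adjusted p = 0.00403) and 2.36 ± 0.43 (SE, adjusted p = 0.00872). SWEET9 (AT2G39060), a sugar carrier of nectaries, went from a signal of 498 ± 247 (SD, n = 3) in bud to 8555 ± 102 in vivo. Of 4 genes of the tapetum, the nurse tissue of the anther, 3 were lower in vivo, and this list also passed with the preset correlation alone. A9 (AT5G07230) went from 3782 ± 128 in bud to 14.8 ± 9.37 in vivo, and SHT (AT2G19070), a spermidine acyltransferase of the tapetum, from 3202 ± 861 to 14.6 ± 8.75.

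By list, 3 of 4 measured genes for the pollen cell wall and secreted peptides rose, with LRX11 as the third, and 4 rose when adjusted over the list alone. These 4 are all LRX genes. Its members RALF25 and RALF26 were not counted, though RALFL25 and RALFL26 had probe sets and are described below. The list had a median log2 fold of 2.61 (adjusted p = 8.13e-07, and adjusted p = 0.136 with an estimated correlation). Of 5 measured surface receptors and ROP signalling genes 2 rose, and 5 when adjusted over the list alone; the median was 1.48 (adjusted p = 7.85e-07, and adjusted p = 0.136 with an estimated correlation). ANX1 had a log2 fold of 1.46 with adjusted p = 0.173, so it was not called. Of 4 tapetum and early anther markers 3 fell, also when adjusted over the list alone, with a median of -5.45 (adjusted p = 7.85e-07, and adjusted p = 0.136 with an estimated correlation). The regulator AMS fell by 4.17 and the receptor EMS1 had a log2 fold of -0.09. Of 3 sperm and generative cell markers 1 fell, also when adjusted over the list alone: the tetraspanin TET11 fell by 3.45. The sperm list had a median of -0.73 (adjusted p = 0.0297, and adjusted p = 0.137 with an estimated correlation). None of 9 pollen vegetative transcription factors was called, and 1 rose when adjusted over the list alone. Their median was 0.32 (adjusted p = 0.0461, and adjusted p = 0.655 with an estimated correlation).

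The other lists did not pass the test between in vivo and bud. Of 6 cytoskeleton and vesicle traffic genes, PLIM2A, an actin-bundling protein, rose by 2.59 and XIE, a myosin, fell by 2.64 (list adjusted p = 0.541), with 3 rising and 2 falling when adjusted over the list alone. Of 4 guidance and reception genes, the receptor-like kinase MDIS1 rose by 1.80 (list adjusted p = 0.524), the same count as when adjusted over the list alone. The sugar carrier list, too small to test, held SWEET8, a glucose carrier of the anther, which fell by 3.11, and STP10, with a log2 fold of 0.94 (adjusted p = 0.330). When adjusted over the list alone, 1 of these carriers rose and 1 fell. No member was called, over all genes or when adjusted over the list alone, of photosynthesis (0 of 6, list adjusted p = 0.703), pistil, style and ovule markers (0 of 8, 0.756), sepal, petal and floral identity genes (0 of 3, 0.872), cell cycle and DNA replication (0 of 3, 0.785), hypoxia response (0 of 3, 0.785), endoplasmic reticulum protein folding (0 of 4, 0.524) and touch, wound and early stress response (0 of 5, 0.683). The same holds for heat shock (0 of 2) and ion transport (0 of 1), which were not tested. The hypoxia list had a median of 0.13 but a mean of -0.08 and a test direction of lower. The photosynthesis members, genes of green tissue, stood at a median log2 fold of -0.12; PSAN, a photosystem subunit, had 13372 ± 2846 (SD, n = 3) in bud and 8954 ± 3230 in vivo.

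By the naming rule, the largest rises from bud to in vivo were led by CYP71B31 (AT3G53300), a cytochrome P450, with a log2 fold of 5.50 ± 0.54 (SE, adjusted p = 0.000139). Then came AT3G55870 (4.50), SWEET9 (4.21 ± 0.48 SE, adjusted p = 0.000392), AT1G30710 of the berberine bridge enzyme-like family (4.16), AT3G54240 (4.14) and the terpene synthase AT3G25810 (3.85). The others were AT3G21570, the strictosidine synthase-like AT1G74010, AT1G54070, the endoglucanase GH9B11, the carboxypeptidase-like scpl38 and AT4G12530, at 3.80 to 3.59. The largest falls were AT1G68875, which fell by 8.49 ± 0.60 (SE, adjusted p = 1.98e-05), and AT1G66850, of the lipid transfer protein family, which fell by 8.27 ± 0.90 (SE, adjusted p = 0.00029). AT3G52130, AT5G62080 and AT4G14815, also of lipid transfer protein type, fell by 7.51, 7.38 and 7.27. ATA27, a glucosidase-like anther gene, fell by 7.50 and the cysteine-rich peptide gene LCR66 by 7.45. AT5G61605, AT1G02813, AT5G48210, A9 and AT1G33430 had log2 folds between -7.13 and -6.86.

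Between in vivo and bud, limma called 915 of 22746 probe sets, 489 higher and 426 lower in vivo, and 2651 had an unadjusted p under 0.05. In all 915 the in vivo and bud arrays did not overlap, which held for 22.0% of all probe sets against 10% by chance. The count was 579 with an offset of 1, 1378 with the 6 arrays alone, and 541 to 585 with bud replicate 2, bud replicate 3 or any in vivo replicate left out. In these settings, other than the 6 arrays alone, more were lower than higher: 262 higher and 317 lower with an offset of 1, 252 and 296 without bud replicate 2, 218 and 323 without bud replicate 3, and 262 and 306, 275 and 303, and 251 and 334 without in vivo replicates 1, 2 and 3. Calls were lost under some of 16 alternatives for MDIS1 (past in 5), LRX11 (8), AT1G54070 (11), PLIM2A, XIE and AT3G21570 (12 each), AT4G12530 (13), ANX2 (14) and AMS (15). The transcription factor list was past in 7 of 18 settings and the sperm list in 12 of 17.

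**Figure D1:**
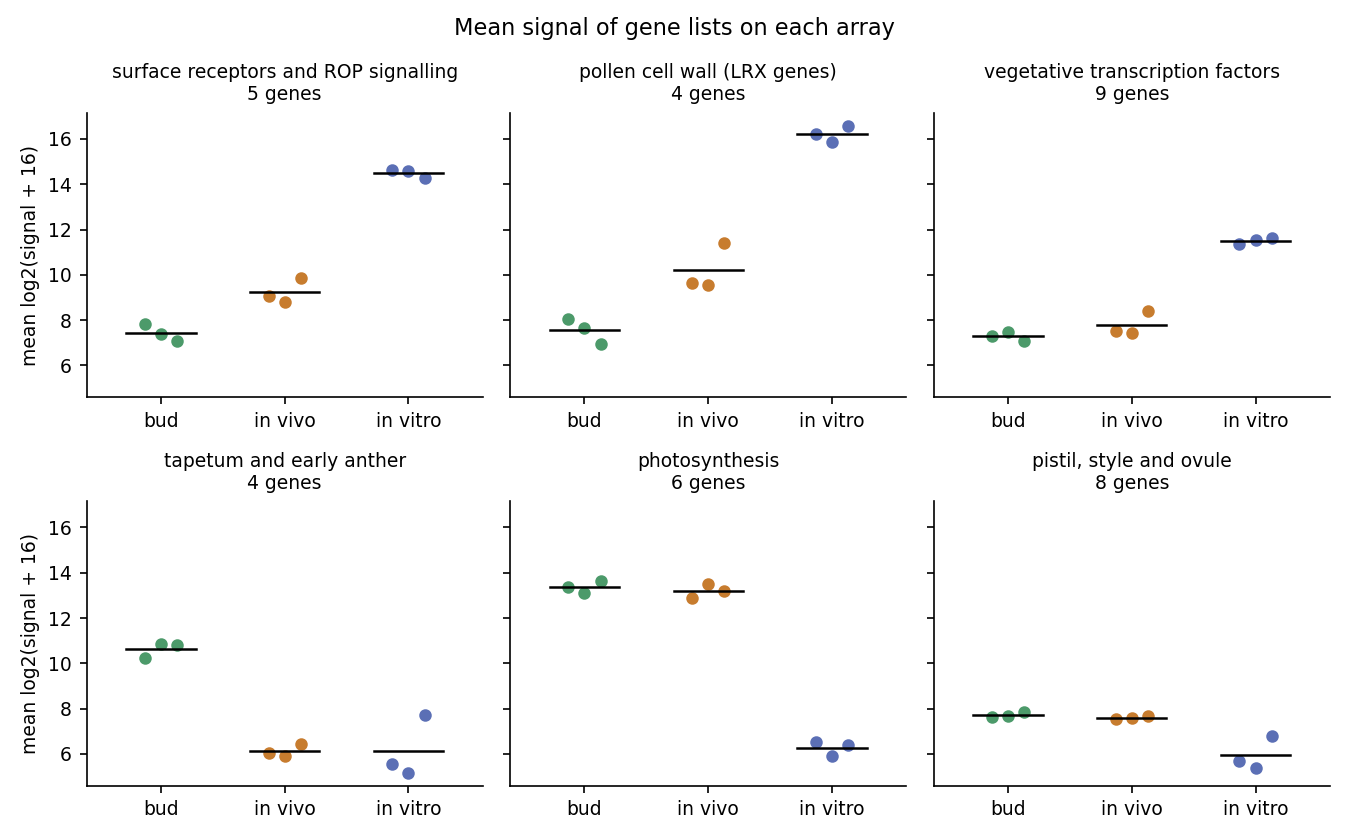
Mean log2(signal + 16) of the measured genes of 6 lists on each array, by group; each point is 1 of 9 arrays and the black line is the mean of 3. The photosynthesis list (6 genes) is near 13 in bud and in vivo and near 6 in vitro, and the tapetum list (4 genes) is near 6 on the in vivo arrays.

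The comparison of in vitro with bud asked how cultured pollen tubes differ from buds. Genes of the pollen tube surface and wall were far brighter in vitro, and photosynthesis genes were far dimmer. All 5 surface receptors and ROP signalling genes rose, with ANX2 at a log2 fold of 8.03 ± 0.43 (SE, adjusted p = 9.71e-08) and ANX1 at 6.95 ± 0.49 (SE, adjusted p = 3.89e-07). All 4 LRX genes rose, among them LRX11 at 9.07, and BUPS1 reached a signal of 74127 ± 21448 (SD, n = 3) from 308 ± 88.0 in bud. All 6 photosynthesis genes fell: PSAN fell by 8.67 ± 0.38 (SE, adjusted p = 6e-08) and LHCB4.2, an antenna protein, fell by 7.83 ± 0.33 (SE, adjusted p = 5.97e-08).

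By list, the test passed for surface receptors (median 6.95, adjusted p = 2.43e-05, and adjusted p = 0.173 with an estimated correlation). It passed for the pollen cell wall (median 8.69, adjusted p = 0.00018, and adjusted p = 0.176 with an estimated correlation). Among pollen vegetative transcription factors 8 of 9 rose, such as BZIP18 (AT2G40620, 4.93); the median was 4.32 (adjusted p = 6.69e-06, and adjusted p = 0.173 with an estimated correlation). All 6 cytoskeleton and vesicle traffic genes rose, such as the pollen actin ACT12 (4.28) and PLIM2A (5.98), with a median of 3.82 (adjusted p = 0.000413, and adjusted p = 0.176 with an estimated correlation). The cell cycle list was chosen to mark other, dividing cells, so its name may mislead, and 3 of its 31 members were measured. These 3 rose, the mitotic kinases AUR1 (3.76) and AUR2 (4.28) and the replication factor PRL (1.37), with a median of 3.76 (adjusted p = 0.00999, and adjusted p = 0.173 with an estimated correlation). Photosynthesis had a median of -7.37 (adjusted p = 0.000413, and adjusted p = 0.173 with an estimated correlation). For these 6 lists the counts adjusted over the list alone equalled those over all genes.

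The other lists did not pass the test between in vitro and bud. All 4 tapetum markers fell, with a median of -4.55 (list adjusted p = 0.072). Of 8 pistil, style and ovule markers 5 fell, led by the receptor FER, which fell by 6.19 (list adjusted p = 0.234). Of 4 guidance genes 2 rose, MDIS1 (7.84) and the cation exchanger gene CHX21 (4.22), with list adjusted p = 0.076. Of 3 sperm markers the male-gamete histone gene HTR10 rose, from a signal of 262 to 4491 (list adjusted p = 0.0914). Of 3 floral identity genes RBE rose by 1.41 (list adjusted p = 0.234). Its signals were dim and overlapped: 64.1, 26.2 and 9.58 in bud, and 61.6, 74.8 and 212 in vitro, where replicate 3 was brightest. All 3 hypoxia genes fell (list adjusted p = 0.165). Of 5 touch and wound genes 2 rose, PUB22 and PUB23, and 3 fell, ZAT10, WRKY53 and CML38 (list adjusted p = 0.825). Of 4 endoplasmic reticulum genes BZIP28 rose and the chaperones CRT1B and ERDJ3B fell (list adjusted p = 0.837). Counts adjusted over the list alone were the same for these lists, except that 2 endoplasmic reticulum genes rose. In the small untested lists, with the same counts when adjusted over the list alone, both heat shock genes rose, HSP22.0 by 5.52 and ROF2 by 6.12; GLR1.2 rose by 1.01, STP10 rose by 6.67 and SWEET8 fell by 1.93. Under quantile or equal-median scaling, 1 of 3 hypoxia genes was lower, in place of 3, and all 3 sperm markers and all 3 floral identity genes were higher. The pistil markers had 3 lower and 1 higher with quantile normalization, and 3 lower and 3 higher with equal medians. The touch and wound list had 2 lower with quantile normalization, in place of 3. With equal medians SWEET8 was not called, 3 guidance genes and all 9 transcription factors rose, and the endoplasmic reticulum list had 2 higher and 2 lower. Calls were lost under some of 16 alternatives for GLR1.2 (past in 11), RBE (12), PUB22 (14), CML38 and SWEET8 (15 each).

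By the naming rule, the largest rises from bud to in vitro were AT1G67640, an amino acid transporter gene, at 10.09 ± 0.30 (SE, adjusted p = 3.32e-08), and AT3G19690, for a cysteine-rich secretory protein, at 10.03 ± 0.53 (SE, adjusted p = 9.07e-08). AT1G06540, AT5G20390, AT3G27410, AT4G33860, the phosphatidylinositol phosphate kinase gene PIPK11, AT4G39610, AT1G04470, scpl38, AT5G12000 and AT1G66210 rose by 9.82 to 9.10. The largest falls were those of AT1G66850, which fell by 9.62, and AT1G68875, which fell by 9.06. AT5G22430 fell by 8.88 and the thionin gene THI2.1 fell by 8.87 ± 0.91 (SE, adjusted p = 6.19e-06). Ribosomal protein genes were among the rest: AT4G16720 fell by 8.59, AT5G20290 by 8.51 and AT3G02080 by 8.11. PSAN, AT4G29030, the defensin gene LCR69, EXO and ATA27 had log2 folds between -8.67 and -7.99.

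Between in vitro and bud, limma called 13859 probe sets, 4645 higher and 9214 lower in vitro (33.5% higher). This split depended on scaling: it was 6827 higher and 6232 lower with quantile normalization, and 9490 higher and 6154 lower with equal array medians. The median log2 fold of all probe sets, against which the folds above are to be read, was -0.42, and it was 0.22 with quantile normalization and 0.63 with equal medians. Arrays did not overlap in 63.8% of all probe sets, against 10% by chance, and 14686 had an unadjusted p under 0.05.

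The comparison of in vivo with in vitro asked how pollinated flowers differ from cultured tubes. Genes of the pollen tube surface and wall were lower in vivo and photosynthesis genes were higher. All 5 surface receptors fell, with ANX2 at a log2 fold of -5.66 ± 0.43 (SE, adjusted p = 8.77e-07), and all 4 LRX genes fell, LRX8 by 5.19 ± 0.47 (SE, adjusted p = 3e-06). All 6 photosynthesis genes were higher in vivo, with PSAN at 8.05 ± 0.38 (SE, adjusted p = 1.05e-07). FER was higher by 6.24 ± 0.34 (SE, adjusted p = 1.61e-07), and both heat shock genes were lower, HSP22.0 with 57.4 ± 30.6 (SD, n = 3) in vivo and 5036 ± 438 in vitro.

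The list medians in vivo against in vitro were -5.40 for surface receptors (adjusted p = 8.83e-05, and adjusted p = 0.138 with an estimated correlation) and -6.04 for the cell wall (adjusted p = 0.000473, and adjusted p = 0.172 with an estimated correlation). Of 9 transcription factors 8 fell, with a median of -3.85 (adjusted p = 1.08e-05, and adjusted p = 0.138 with an estimated correlation). All 6 cytoskeleton genes fell, with a median of -3.29 (adjusted p = 0.000256, and adjusted p = 0.153 with an estimated correlation). The 3 measured of 31 cell cycle genes fell, with a median of -3.54 (adjusted p = 0.00762, and adjusted p = 0.138 with an estimated correlation). All 3 sperm markers fell, HTR10 by 4.11 and TET11 by 3.95, with a median of -3.95 (adjusted p = 0.0114, and adjusted p = 0.138 with an estimated correlation). Photosynthesis had a median of 7.17 (adjusted p = 0.000365, and adjusted p = 0.138 with an estimated correlation). For these 7 lists the counts adjusted over the list alone equalled those over all genes.

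Lists that did not pass between in vivo and in vitro included pistil markers, with 4 higher, among them NGA1 (3.28) and ALC (3.37), and 1 lower of 8 (list adjusted p = 0.323). Of 4 guidance genes 2 fell, MDIS1 by 6.04 and CHX21 by 4.16 (list adjusted p = 0.0801). Of 4 tapetum markers 1, EMS1, was higher (list adjusted p = 0.706), with a median of -0.84, a mean of -0.01 and a test direction of lower. Of 3 floral identity genes 2 fell (0.303), and 2 of 3 hypoxia genes were higher (0.222). The touch and wound list had 3 higher and 2 lower of 5 (0.807), and the endoplasmic reticulum list 2 higher and 1 lower of 4 (0.912). Counts adjusted over the list alone were the same, except for 2 lower endoplasmic reticulum genes. In the untested lists, with the same counts over the list alone, both heat shock genes, both sugar carriers and GLR1.2 (past in 12 of 16 alternatives) were lower in vivo. With equal medians 3 pistil markers were higher and 2 lower, and 3 tapetum markers were lower and 1 higher. Pistil markers were 3 higher and 1 lower with quantile normalization. With quantile normalization and with equal medians 1 of 3 hypoxia genes was higher, in place of 2 (median 2.13, and 0.98 and 1.11 with these scalings), and all 3 floral identity genes and all 9 transcription factors were lower. With quantile normalization 5 of 6 cytoskeleton genes were lower, and the touch and wound list had 2 higher and 2 lower. With equal medians the endoplasmic reticulum list had 2 higher and 2 lower.

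By the naming rule, the largest rises from in vitro to in vivo were those of THI2.1 (9.26 ± 0.91 SE, adjusted p = 5.25e-06) and AT5G45950, a lipase-family gene (9.12 ± 0.34 SE, adjusted p = 7.96e-08). GILT, AT3G20820, the plantacyanin gene ARPN, PSAN, AT1G13930, the ribosomal protein gene AT4G16720, AT5G22580, AT2G28790, AT1G29670 and the ribosomal protein gene AT5G20290 followed at 8.81 to 7.79. The largest falls were AT3G19690, which fell by 9.91, and AT1G67640, which fell by 8.51. The small heat shock protein genes AT1G53540 and AT2G29500 fell by 8.36 and 7.72, and the calmodulin-like gene AT1G76640 fell by 8.34. AT3G15860, AT5G26100, AT1G61080, AT4G33860, AT4G26830, AT5G46200 and AT5G09280 had log2 folds between -8.28 and -7.02.

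Between in vivo and in vitro, limma called 13495 probe sets, 8953 higher and 4542 lower in vivo (66.3% higher). With quantile normalization the split was 5986 higher and 6847 lower, and with equal medians 6037 higher and 9382 lower. The median log2 fold of all probe sets was 0.36, and it was -0.26 with quantile normalization and -0.67 with equal medians. Arrays did not overlap in 63.5% of all probe sets, against 10% by chance, and 14360 had an unadjusted p under 0.05.

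**Figure D2:**
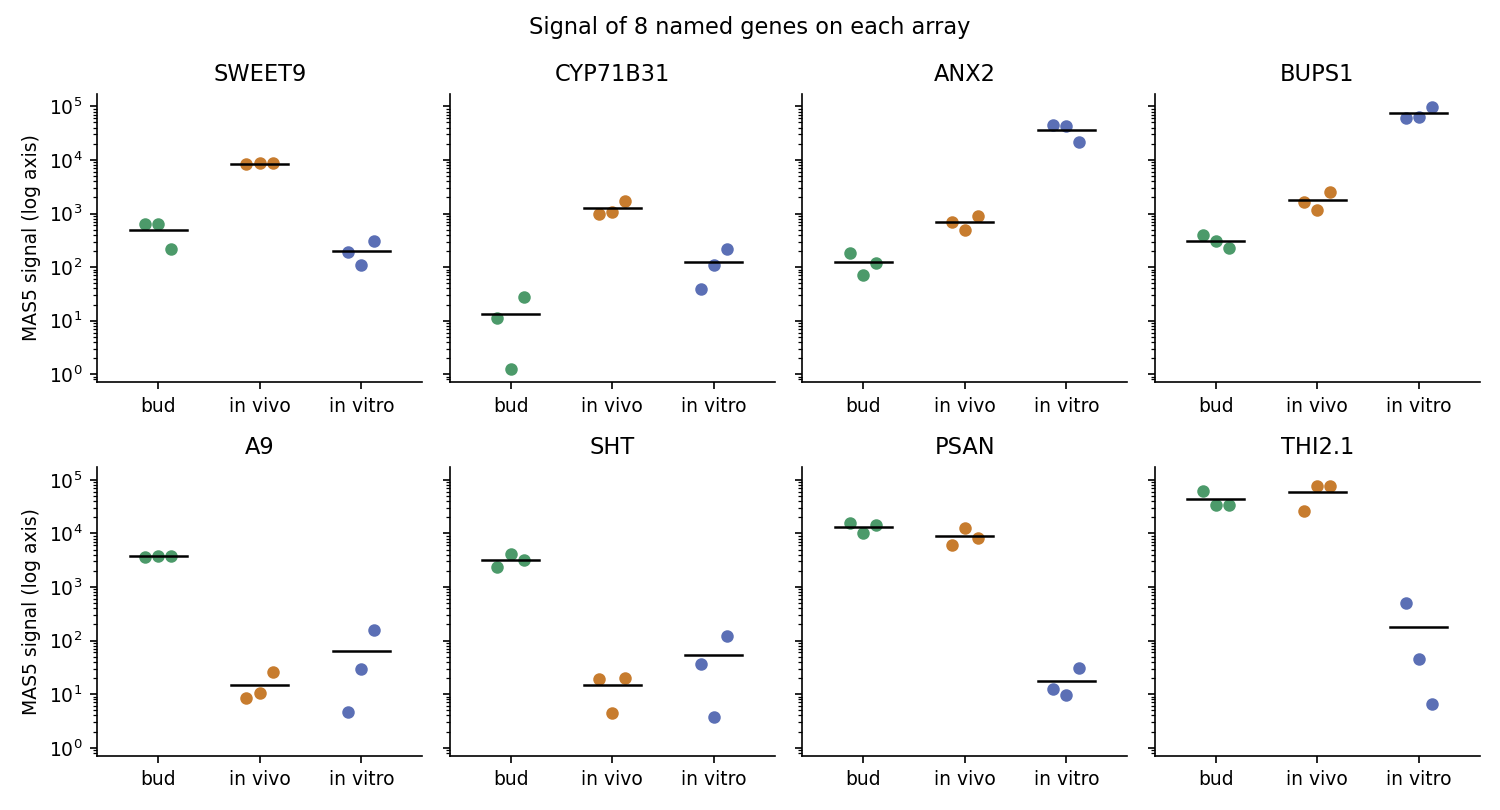
MAS5 signal of 8 named genes on each array, on a log axis, by group; each point is 1 of 9 arrays and the black line is the mean of 3. SWEET9 and CYP71B31 are highest in vivo, ANX2 and BUPS1 are highest in vitro, and PSAN and THI2.1 are lowest in vitro.

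The set higher in vivo than in both other groups addresses what is particular to the pollinated flower sample. Its genes with the largest smaller-of-both folds were AT3G55870, SWEET9, AT3G25810, AT4G12530 and CYP71B31. SWEET9 had a signal of 202 ± 101 (SD, n = 3) in vitro, and AT3G25810 had 411 ± 280 in bud, 5255 ± 3044 in vivo and 172 ± 68.4 in vitro. UPB1, a transcription factor of the bHLH family, had 151 ± 106 in bud, 1434 ± 174 in vivo and 20.6 ± 13.9 in vitro. LPR1, a multicopper oxidase that acts in phosphate sensing, had 142 ± 36.1 in bud, 1288 ± 344 in vivo and 16.3 ± 8.16 in vitro. AT3G56610, the cysteine-rich peptide gene LCR80, the short-chain dehydrogenase-like AT2G29340, AT3G24510 and AT3G10320 completed the named genes. The set held 183 probe sets, 108 of them with a named gene, where independent calls would share 192, so the overlap was not larger than that. Simulations without effect shared 0, which follows from the threshold and lends the set no support. Across probe sets, the log2 folds of both contrasts correlated at -0.037, against 0.500 in simulations where the shared in vivo arrays alone link them. The covariance was -0.072 against 0.125. In vitro, 142 of the 183 were below the median probe set, and against bud 99 were lower in vitro, 6 higher and 78 not called. The count was 58 with an offset of 1, 351 with an offset of 64, 115 with quantile normalization, 67 to 116 with any single bud or in vivo array left out, and 306 without in vitro replicate 3. The call of AT4G12530 in vivo against bud was past in 13 of 16 alternatives and that of AT3G56610 in 15.

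The set changed alike in vivo and in vitro against bud addresses what the pollinated flower sample and cultured tubes share. Both samples were higher than bud for the LRX8, LRX9, BUPS1 and ANX2 genes, and for AT1G30710, GH9B11 and scpl38. Both were lower for A9, SHT, AMS, ATA27 and AT1G68875. Of the probe sets tested, 307 rose and 340 fell in both, 647 in all. Independent calls would share 99.9 and 173, which does not allow for the shared bud arrays. Simulations without effect shared 0, which follows from the threshold. With quantile normalization 306 rose and 250 fell, and with equal medians 348 rose and 257 fell. The log2 folds of both contrasts correlated at 0.354 across probe sets, which are not independent replicates, against 0.500 in simulations in which the shared bud arrays alone link them; the covariance was 0.731 against 0.125. The split was 173 higher and 240 lower without bud replicate 2 (413), 138 and 267 without bud replicate 3 (405), 189 and 254 without in vivo replicate 1 (443), and 140 and 271 without in vivo replicate 3 (411).

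**Figure D3:**
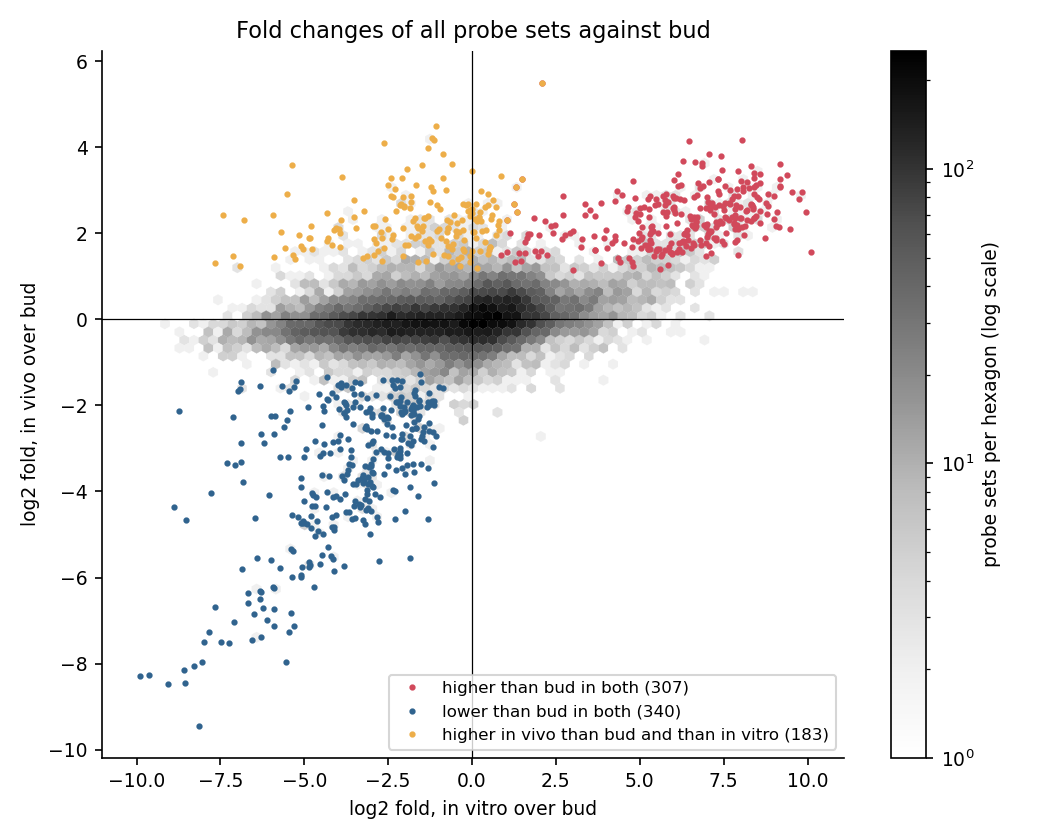
Log2 fold of in vivo over bud (vertical) against log2 fold of in vitro over bud (horizontal) for all 22746 probe sets; grey hexagons give the number of probe sets on a log scale. Points mark the 307 probe sets higher and the 340 lower than bud in both, and the 183 higher in vivo than in both other groups.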

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

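Of the tests below, those of scaling and of photosynthesis genes were chosen after the results were seen; the marker test was added after the in vivo set was seen, before its markers' values were.

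In 99 probe sets the signal was higher in vivo and lower in vitro than in bud, and in 31 it was lower in vivo and higher in vitro; each stands out because its change from bud had opposite signs in vivo and in vitro, with the in vivo and in vitro difference itself past the limma test. Examples chosen after their values were seen are the metallothionein gene MT1C (473 in bud, 2668 in vivo, 46.8 in vitro) and CHX19 (479, 17.7 and 1690). Independent calls would share 198 and 87.0. The median signal of the hybridisation controls, 78112 on in vitro replicate 3, stands out as a signal outside the tested probe sets that is above every bud array (12719 to 17569).

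The 307 probe sets higher than bud both in vivo and in vitro, LRX8, LRX9, BUPS1 and ANX2 among them, had a median log2 difference of in vivo from in vitro of -4.21 (upper quartile -2.87), while 6 of them, such as CYP71B31, were called higher in vivo than in vitro. Not every gene of the pollen lists rose over bud in vivo, since SWEET8, XIE and TET11 fell. Without 1 array the 307 were as few as 138 (bud replicate 3), 140 (in vivo replicate 3), 173 (bud replicate 2) and 189 (in vivo replicate 1). The tables argue against the authors' scaling as the source of this gap. With quantile normalization the median log2 difference of in vivo from in vitro was still -3.45 (upper quartile -1.74) for the same probe sets. Equal medians move every probe set of an array alike and could here only widen the gap (to -5.235), so that setting is no test of it. RNA of other floral cells in the in vivo pull-down is consistent with the photosynthesis genes, whose median was 7.17 higher in vivo than in vitro on the log2 scale and -0.12 from bud, as for PSAN (8954 in vivo, 13372 in bud). The tagged ribosome was meant to keep such RNA out, and all 6 of these genes are active in green floral tissue. The bud arrays were about as bright for these genes and held tapetum signal, such as A9 (3782). RNA of other cells may therefore be part of the bud pull-down too, which was not tested. A lower activity of the same genes in tubes within the flower stays open and was not tested.

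The 183 probe sets higher in vivo than in both other groups may come from tubes in the pistil, which was not tested, from cells of the open flower, or in part from scaling. Of 12 markers of nectary, stigma and open flower, 5 were measured and 3 had not been looked at. These 3 had a median log2 difference in vivo from bud of 0.43. TPS11 was higher in vivo (8246, against 2647 in bud, limma adjusted p = 0.0489, and 43.8 in vitro). BSMT1 was lower in vivo than in bud. JMT was not called against bud (850 in vivo, 621 in bud). It was brightest in vitro (7214), so it does not separate flower cells from tubes. The source of the set therefore cannot be told apart on 3 markers that go both ways. SWEET9 and AT3G25810, nectary and stigma genes already seen, were both in the set. Under quantile normalization 57.4% of the set (105) kept both calls and under equal medians 74.3% (136), which lies between the bounds set for and against scaling. Of 100 assignments of the 9 arrays to 3 groups, the real one among them, 4 gave as many probe sets, and the highest other gave 3834. This share cannot decide about chance for the set. Assignments that mix in vitro arrays with others take up the large in vitro difference as spread within groups.

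More probe sets were lower than higher in vitro against bud. Whether scaling each array to one trimmed mean lies behind this cannot be told apart: 60.7% of the called probe sets were higher in vitro with equal array medians, against 33.5% as deposited, but that setting moves every probe set of an array alike, so the direction of this move follows from its construction. With quantile normalization 52.3% were higher (6827 higher and 6232 lower); it does not move all probe sets alike, but it gives every array one distribution, which pulls the split towards balance whatever the source. The third in vitro array is argued against, since without it 32.1% were higher. A true difference in how many genes are translated in tubes stays open and was not tested.

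For the contrasts, 1 of 10 splits of the 6 arrays, the real one, gave as many changed probe sets: 915 for in vivo with bud, 13859 for in vitro with bud and 13495 for in vivo with in vitro, with 0 in the highest other split of each. Splits of 6 arrays are too few for a share under 0.05. For the 647 probe sets changed alike in vivo and in vitro against bud, 2 of 100 assignments of all arrays, the real one among them, gave as many. The highest other gave 12052. Here too the large difference of the in vitro arrays enters the drawn groups, so this share cannot decide about chance.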

How the results depend on the processing

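Added after the data were seen were the fit without the arrays with the brightest and dimmest hybridisation controls, equal medians for named genes, and the fit to 6 arrays for the shared sets. The counts against in vitro, 13859 and 13495, stayed within 1.5 times under every alternative run. Their members moved more with scaling: 10735 of the 13859 and 10350 of the 13495 stayed called in the same direction with quantile normalization. With equal medians 10799 and 10579 did. The 915 of in vivo with bud became 579 with an offset of 1 and 1378 with the 6 arrays alone; with an offset of 1 its split of 489 higher and 426 lower turned to 262 and 317. The 183 became 58 with an offset of 1 (55 shared), 351 with an offset of 64 (177 shared), 115 with quantile normalization (105 shared) and 323 with the 6 arrays alone (181 shared). Lists past the test for in vivo with bud went from 5 to 3 with an offset of 64. With an estimated correlation 0 of 5, 0 of 6 and 0 of 7 stayed past. Lists with large shifts in every member did not pass then either. Photosynthesis, with all 6 genes lower in vitro than bud, had a camera adjusted p of 0.173. SWEET9 and AT2G29340 were lower in vitro than bud (-1.19 and -1.21), SWEET9 close to the threshold (limma adjusted p = 0.0477). With quantile normalization SWEET9 stood at 0.11 (adjusted p = 0.844) and AT2G29340 at 0.12 (adjusted p = 0.79), each p the highest of 16 alternatives. JAG, at 0.02 between in vivo and in vitro, stood at -1.01 with quantile normalization and with equal medians. Apart from fits that use fewer arrays, the cause was not tested.

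Leaving out single arrays gave 541 to 1292 for in vivo with bud, 12539 to 14417 for in vitro with bud, 12016 to 14045 for in vivo with in vitro, 67 to 306 for the 183, 405 to 847 for the 647, and 3 to 5, 6 to 8 and 7 to 7 lists. The 915 became 548 without bud replicate 2, 541 without bud replicate 3, and 568, 578 and 585 without in vivo replicates 1, 2 and 3, and in each of these 5 fits more were lower than higher (218 higher and 323 lower without bud replicate 3). The 183 became 108, 82 and 83 without bud replicates 1, 2 and 3, 77, 67 and 116 without in vivo replicates 1, 2 and 3, and 306 without in vitro replicate 3. The 647 became 413 without bud replicate 2, 405 without bud replicate 3 and 411 without in vivo replicate 3, and the 307 higher among them became 173, 138 and 140, and 189 without in vivo replicate 1. Without bud replicate 1, 3 lists passed for in vivo with bud. Without in vitro replicate 3 and in vivo replicate 1 together the counts were 876, 14081, 12978, 161 and 625.

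With the replicate number as a block the counts were 784, 13844, 13412, 153 and 557. Same-numbered arrays correlated at -0.0458 to 0.0735 in their deviations from the group mean, below 0.1 in each of 9 pairs, so the samples were taken to share only a number. As a hint from the data that goes both ways, 6 of 9 arrays had the best partner among both other groups under their own number, and 1 of 9 correlated best with its own number in each of them. Over all alternatives but the single arrays left out, 49 results for named genes became called, 62 lost the call and 4 turned sign. For lists, 8 became called and 25 lost the call. With 1 array left out in turn, 29 results for named genes became called and 94 lost the call, and 2 list results became called and 8 lost the call. With quantile normalization 291 called probe sets of in vitro with bud turned sign, and 307 of in vivo with in vitro. Of these, 0 and 1 were also called with the turned sign. Dim signals limit the folds: the offset of 16 sets the floor, and a fold against a signal near it is compressed.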

Other observations

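Gene families read from shared symbols were grouped after the data were seen, as were the pollen-rich probe sets below; 29 families with at least 8 members were tested and 5 are described. Of 14 SWEET sugar carriers, 2 rose in vivo against bud, SWEET9 and SWEET14 (1.88), and 3 fell, SWEET8, SWEET3 and SWEET7 (adjusted p = 0.611). In vitro 11 SWEET genes were lower than bud and 1 higher (adjusted p = 0.0688). With quantile normalization 10 were lower and 2 higher (adjusted p = 0.0375) and SWEET9 turned sign, and with equal medians 9 were lower and 2 higher (adjusted p = 0.0276), so the family passed under both with the preset correlation. With an estimated correlation, run on the deposited scale alone, the adjusted p was 0.535. Of 11 RALF-like peptide genes, 2 were higher in vitro than bud, 3 with quantile normalization and 4 with equal medians: RALFL26 had 641 ± 445 in bud, 5120 ± 1236 in vivo and 169095 ± 131894 in vitro, and RALFL25 had 2185 ± 1024, 12734 ± 3837 and 74241 ± 31115. Another 6 RALF-like genes, such as RALFL34 (8259 ± 1231 in bud, 37.9 ± 32.0 in vitro), were lower in vitro, 6 also with either scaling (family adjusted p = 0.526). On the deposited scale 3 RALF-like genes were higher in vivo than bud (family adjusted p = 0.115). Against in vitro, 7 were higher in vivo and 2 lower (family adjusted p = 0.2415). Of 15 IQD genes, for calmodulin-binding proteins, 13 were lower in vitro (adjusted p = 0.0688), 8 with quantile normalization (adjusted p = 0.0637) and 10 with equal medians (adjusted p = 0.0279, past the threshold), and the adjusted p on the deposited scale was 0.528 with an estimated correlation. Of 26 cytochrome P450 (CYP) genes, 3 rose in vivo against bud (median 0.49, adjusted p = 0.0449, and adjusted p = 0.576 with an estimated correlation), 2 rose with quantile normalization (adjusted p = 0.0851) and 3 with equal medians (adjusted p = 0.0292). Of the 8 plastid rps genes none was called in vivo against bud, with a median of 0.95 (adjusted p = 0.0385, and adjusted p = 0.464 with an estimated correlation; 0.0493 with quantile normalization and 0.0292 with equal medians). In vitro 6 of them were lower than bud (median -2.57, adjusted p = 0.227), 4 with either scaling (0.154 and 0.140). In vivo 7 were higher than in vitro (median 3.90, adjusted p = 0.0663), 6 with either scaling, where the family passed (adjusted p = 0.0279 with quantile normalization and 0.0170 with equal medians); the adjusted p on the deposited scale was 0.419 with an estimated correlation.

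Among 570 probe sets with a log2 fold of at least 5 in vitro over bud, the median signal was 0.995 ± 0.262% (SD, n = 3) of the in vitro mean in bud and 3.10 ± 1.07% in vivo. Among 1011 probe sets with a log2 fold of -5 or lower, the in vivo arrays stood at 76.2%, 87.0% and 79.3% of the bud mean and the in vitro arrays at 1.08%, 0.716% and 0.870%. Both sets were picked by the fold between in vitro and bud, so their low bud and low in vitro values follow from that choice. The actin 3' control had a signal of 20057 ± 2666 in bud, 20131 ± 5618 in vivo and 183 ± 104 in vitro. The brightest 1% of probe sets held 64.1% of all signal on in vitro replicate 3. A total of 133 probe sets were lower in vivo than in both other groups, where independent calls would share 85.1.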
